A study of Drosophila melanogaster with 3 samples.

How the data were processed

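The 3 samples are anti-GFP ChIP-seq libraries of whole prepupae with a C-terminal eGFP fusion to CG6808, numbered as biological replicates 1, 2 and 3 in the labels and placed in 1 group. The antibody field of the labels names CG6808 instead of GFP, and the labels give an age of 24 days, which is unusual for prepupae. The descriptions and the stage field were followed. The labels give DNA fragmentation by sonication with sizes of 200 to 800 bp. Per the file headers in the deposited text descriptions, each replicate's regions were called from its own alignment against 1 control alignment shared by the replicates, on dm6 and again on dm3. A further list came from the pooled replicates, and the optimal IDR list was derived from the 3 replicate lists and the pooled list. The aligner and the peak caller are not given in the sources used here. The control alignment and the coverage tracks were not analysed here.

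The deposited region lists give each region's signal, the authors' peak height over control by the column order of the file format, and it was treated as not scaled between lists, since it was larger in the pooled list. It was used to describe and rank peaks within a list. The deposited −log10 q-value column ranged from 0.191 to 4.23 and was not used to rank. The IDR list was the same set as the 8091 highest-signal regions of the pooled list, and therefore holds 8091 of 8091 in common. Because the replicate lists each hold 30000 regions by construction, equal-length tops of 8091 regions were compared. Of the IDR regions on dm6, 57.6% had the same width, and 768 neighbouring summits were under 250 bp apart, so some peaks may be shoulders of others. Depth was unknown, and intervals on shares cover counting error only.

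Places, genes and sequence were taken on dm6 from Ensembl release 115 and the Release 6 genome, on arms 2L, 2R, 3L, 3R, 4 and X, without transposable elements. The dm3 lists served only for counts, arms and overlap. A promoter summit lay within 500 bp of any annotated TSS, and the other places were taken in the order coding exon, 5' UTR, 3' UTR, other exon, intron. Random placement used 1000 draws on the same arms. Replicate summits were matched within 100 bp. Medians of signal were compared by a two-sided permutation test with 100000 resamples. A gene was bound if a summit lay within 500 bp of any of its TSSs, and each of 24 gene lists was tested against all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Odds ratios have 0.5 added to each cell. Of the symbols written, 6 were not matched. A list is a set of related genes and its members are not independent.

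Motifs (21 consensus sequences and a shuffled version of each) and all 7-mers were sought on either strand within 100 bp of summits. Each peak had 1 control window outside the peaks, at the same offset from an unbound TSS for promoter peaks and on the same arm otherwise, with GC content within 5 percentage points. A 7-mer also needed an odds ratio over 1.5. Names in the text follow a rule fixed before the data were examined. It takes the nearest-TSS genes of the 25 strongest peaks, CG6808, the 3 bound genes of highest signal in each list past the threshold, any unbound members where under 5 remain, and the 5 7-mers of highest odds ratio. Csk and the genes of the closing observations were named after their values were seen.

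The procedures were tested on simulated data. Between 2 independent sets of control windows, 0 of 8192 7-mers and 0 of 21 motifs were called, and 10 of 10 planted 7-mers were recovered. These sets were drawn alike, so the absence of calls does not carry over to real peaks, where 4 shuffled motifs were called higher and 4 lower. A planted gene list was called in 100% of 100 simulations, and 0.174% of 2300 unplanted lists were called. Each gene was drawn as bound independently there, so that rate does not cover lists whose members may share summits. A planted promoter share of 39.5% was measured as 40.0%, and a planted replicate overlap of 69.6% as 70.0%. In 100 simulations without a difference of medians, 6% fell under the threshold.

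Alternatives fixed beforehand were the stronger part of the peaks, peaks matched in every replicate, each replicate left out, the top of the pooled list, other promoter windows, matching distances, list lengths and backgrounds, the other build, and other motif windows and controls. For peak sets, leaving out a replicate kept the IDR peaks matched in the strongest regions of both others. The omitted replicate still helped to define the IDR list. The merged peaks, the 1000 strongest peaks, peaks without the inward-facing core, the length model and the lowest-ranked regions as motif controls were chosen after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.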

Results

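Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster prepupae of pooled sex. The flies carried a transgene for the zinc finger protein CG6808 fused to enhanced GFP, and an antibody to GFP was used, as the sample descriptions state. CG6808 is named Zaf1 in the Release 6 annotation (FBgn0037921, chromosome 3R, 11621466 to 11625644, minus strand). The samples were 3 biological replicates of 1 group, so the design holds no comparison between conditions, and each result asks where the tagged protein was found and how well the replicates matched. Each replicate list and the list from the pooled replicates held 30000 regions. The authors' reproducibility-filtered list (the IDR list, from the irreproducible discovery rate) held 8091 peaks on dm6 and 7453 on dm3. Read depth was unknown, and no untagged or mock sample was analysed here.

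The strongest peaks lay at the same places in all 3 replicates. Among the 8091 strongest regions of each replicate, 69.8% ± 1.63 (SD, n = 3 pairs) had a summit within 100 bp of one in another replicate, against 1.22 to 1.23% for random placement. Across IDR peaks, which are not independent replicates, Spearman's rho of the signal was 0.827 ± 0.00282 (SD, n = 3 pairs). Of the IDR peaks, 96.8% had a summit within 100 bp in the full list of replicate 1, 91.6% in that of replicate 2 and 90.8% in that of replicate 3. Among the 8091 strongest regions of each replicate, 4841 IDR peaks (59.8%) were matched in all 3. This share ran from 94.9% in the strongest quartile to 52.4% and 7.22% in the last 2, where the equal list length limits matching. The median signal of the 8091 strongest regions was 159.6 in replicate 1, 69.5 in replicate 2 and 70.3 in replicate 3.

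The highest peak, with a signal of 24704, lay on 2R at 13963244 to 13964229, in an intron, at an offset of -954 bp from the nearest start site, that of CG42806. The peak at raskol, which encodes a Ras GTPase-activating protein, had a signal of 23405 (X, 17737818 to 17738852). The promoter of MEP-1, which encodes a zinc finger protein of a Mi-2 complex, ranked 3 (3L, 2631050 to 2632024). Next came c12.2, Atox1, tun, CHES-1-like, CG33632, TBPH (the fly ortholog of TDP-43) and CG17746, with signals from 18042 at c12.2 to 14217 at CG17746. The remaining 15 of the 25 strongest peaks were nearest to CG11438, DCTN4-p62, CG5445, lncRNA:CR44032, CG4627, Epg5, Pop2, scf, Tango5, Atet, cal1, Gs1, CG6420, bin3 and Elp5. Pop2 is a deadenylase of the CCR4-NOT complex, cal1 is needed to load the centromeric histone, and Gs1 encodes a glutamine synthetase. Of these 25 peaks, 20 lay in promoters, 3 were intergenic, 1 was intronic and 1 was in a 3' UTR. All 25 ranked within the top 28 of replicate 1, the top 28 of replicate 2 and the top 35 of replicate 3. The nearest start site does not show that a gene is regulated.

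The tagged protein was found at promoters more often than chance placement gives. Of the IDR summits, 35.3% (95% Wilson interval 34.3 to 36.4%) lay within 500 bp of an annotated transcription start site (TSS), against 13.5% for random summits on the same arms. The enrichment was 2.61-fold, with p = 0.000999 in a one-sided permutation test, the smallest value that 1000 placements can give. The replicates gave 35.4% ± 3.38 (SD, n = 3), with 39.3% in replicate 1, 33.9% in replicate 2 and 33.1% in replicate 3. Promoter summits lay upstream of the TSS in 65.3% of cases, at a median offset of -79.5 bp. Coding exons held 0.606% of summits against 13.9% of random ones, and 3' UTRs 0.84% against 4.41%. Introns held 43.7% against 39.3%, and intergenic sequence 17.5% against 27.5%.

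Promoter peaks were most frequent among the 810 strongest peaks, at 48.4% (45.0 to 51.8%), and least frequent among the 809 weakest, at 29.0% (26.0 to 32.3%). The median signal was 300.3 at promoters and 278 elsewhere, a difference of 22.0 (two-sided permutation test, p = 7.0e-05). In each replicate's own values the promoter median was 1.09 ± 0.0314 times that of other peaks (SD, n = 3 replicates). With a promoter window of 250 bp the difference was 11.2 and no longer passed the test (permutation p = 0.0640). Among IDR peaks matched in both other replicates it was 76.2 without replicate 1, 53.8 without replicate 2 and 50.6 without replicate 3.

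**Figure D1:**
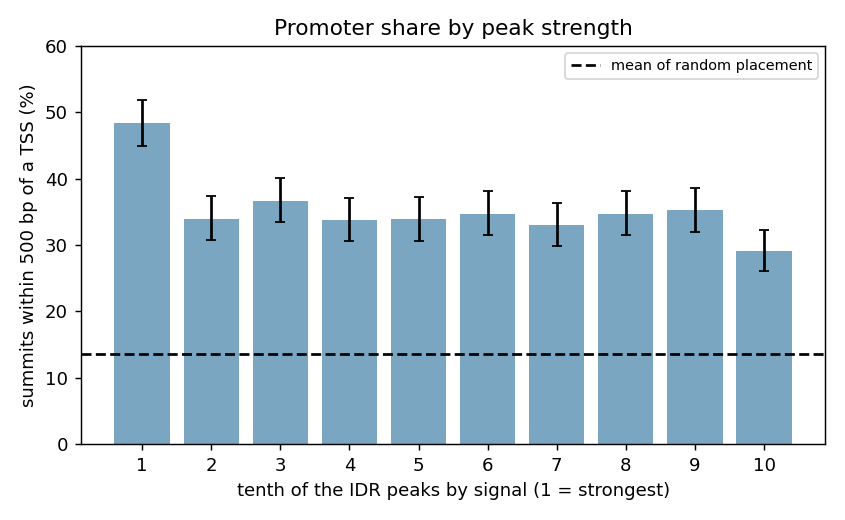
Share of IDR summits within 500 bp of a TSS (vertical axis, percent) in 10 equal groups of peaks ordered by signal (horizontal axis, 1 is the strongest). Bars give the share, error bars the 95% Wilson interval, and the dashed line the mean of random placement, 13.5%. The strongest group stands at 48.4% and the weakest at 29.0%.

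The X chromosome carried 65.7 peaks per Mb and the arms 2L, 2R, 3L and 3R together 59.8 per Mb, a ratio of 1.10. In the replicate lists the ratio was 1.05 ± 0.0285 (SD, n = 3). Chromosome 4 had 22 peaks, or 16.3 per Mb. No test was made of these ratios, since X copy number differs between the pooled sexes.

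Of 13945 protein-coding genes, 2519 (18.1%) had a summit within 500 bp of a TSS, and 18.3% ± 2.19 (SD, n = 3) did in the replicate lists. Among 24 gene lists, 3 were bound more often and 3 less often than other genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the lists). A gene with more TSSs has more sequence in which a summit counts, and the list tests were not adjusted for this. Cytosolic ribosomal protein genes stood furthest above the rest. Of 93, 61 were bound (65.6% against 17.7% of other genes, odds ratio 8.77, 95% interval 5.72 to 13.4, adjusted exact p = 1.15e-22). The replicate lists gave 63.1% ± 11.6 (SD, n = 3). Without the peaks that hold an inward-facing CACTG core (described with the 7-mers), an alternative chosen after the data were seen, the odds ratio was 5.03 (adjusted exact p = 1.57e-11). RpL30 had the highest signal of these genes, 1452 (2L, 19009060 to 19009497, offset -34 bp from the TSS), followed by RpS27 with 931 and RpL34b with 695. These were peaks of middle height, with a median signal of 365 against 335 at all bound genes. Among the 1000 strongest peaks, a set chosen after the data were seen, only 2 of the 93 genes were bound and the odds ratio was 0.732 (adjusted p = 1 by Fisher's exact test).

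Genes of the ecdysone response, the hormone program that drives metamorphosis, were bound in 16 of 29 cases (55.2%, odds ratio 5.57, adjusted exact p = 3.66e-05). Eip93F, a transcription factor of that program, had a peak of signal 1648 (3R, 21972080 to 21972497). E23, an ABC transporter, had 1427 and Eip75B, a nuclear receptor, had 1268. Heat shock and chaperone genes were bound in 11 of 22 cases (odds ratio 4.55, adjusted exact p = 0.00259). Hsp27 led them with 3142 (3L, 9383637 to 9384141, offset -148 bp from the TSS), followed by Hsp83 with 1179 and Hsp26 with 882. With a promoter window of 250 bp the heat shock list did not pass (odds ratio 3.01, adjusted exact p = 0.0891). Reads of the near-identical Hsp70 copies may be shared, so their status is uncertain. In the replicate lists the bound share was 51.7% ± 9.12 for the ecdysone list and 45.5% ± 9.09 for the heat shock list (SD, n = 3 each).

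Chemoreceptor, cuticle protein and histone genes were bound less often than other genes. None of 179 chemoreceptor genes had a promoter summit (odds ratio 0.0124, adjusted exact p = 4.52e-15), and 3 of 122 cuticle protein genes did (2.46%, odds ratio 0.132, adjusted exact p = 1.0e-06). Those 3 were Cpr72Ea, with a signal of 295, Cpr51A with 194 and Lcp65Ad with 175. None of 111 replication-dependent histone genes was bound (odds ratio 0.0201, adjusted exact p = 3.17e-09), but these are near-identical repeated copies and the result is uncertain. Several of these calls were lost with a narrower background. Among only the genes with a pooled region within 500 bp of a TSS, ribosomal protein genes were higher (odds ratio 5.79, adjusted exact p = 2.41e-07), and chemoreceptor (0.0339, adjusted p = 0.00140) and Hox cluster genes (0.0521, adjusted p = 0.0252) were lower. The ecdysone (odds ratio 1.53, adjusted exact p = 0.676), heat shock (2.58, adjusted p = 0.561), cuticle (0.365, adjusted p = 0.561) and histone lists (0.784, adjusted p = 1) no longer passed. None of the 24 lists passed with the 1000 strongest peaks, which bound 500 genes, and 6 had an unadjusted p under 0.05 in Fisher's exact test. The odds ratio there was 4.84 for the heat shock list, 3.56 for the ecdysone list and 0.109 for the cuticle list, and 0 chemoreceptor and histone genes were bound.

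The other 18 lists did not pass the threshold. Nearest to it from above were autophagy genes (8 of 20, adjusted exact p = 0.0617), Polycomb and trithorax group genes (10 of 28, adjusted p = 0.0720) and developmental patterning genes (14 of 45, adjusted p = 0.0832). The Polycomb and trithorax list passed without replicate 1 (odds ratio 3.02), replicate 2 (3.31) or replicate 3 (3.12). Autophagy genes passed without replicate 3 (3.55) and had an odds ratio of 1.98 without replicate 1, and patterning genes had 1.32 without replicate 2. Among other housekeeping families, the counts of bound genes were 9 of 87 oxidative phosphorylation genes, 2 of 32 proteasome genes, 11 of 51 translation factors and 14 of 73 mitochondrial ribosomal protein genes. The oxidative phosphorylation list passed as lower without replicate 1 (odds ratio 0.2996 against 0.547, adjusted exact p = 0.0272). Counts of bound genes were 7 of 37 for replication and cell cycle, 5 of 17 for chromatin boundary proteins, 3 of 16 for ZAD zinc finger genes and 3 of 15 for ecdysone synthesis. They were 4 of 28 for muscle structure, 6 of 29 for neuronal function, 4 of 16 for cell death, 1 of 12 for fat body proteins and 1 of 26 for testis genes. No gene of 11 Hox cluster genes or 20 glue genes was bound.

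**Figure D2:**
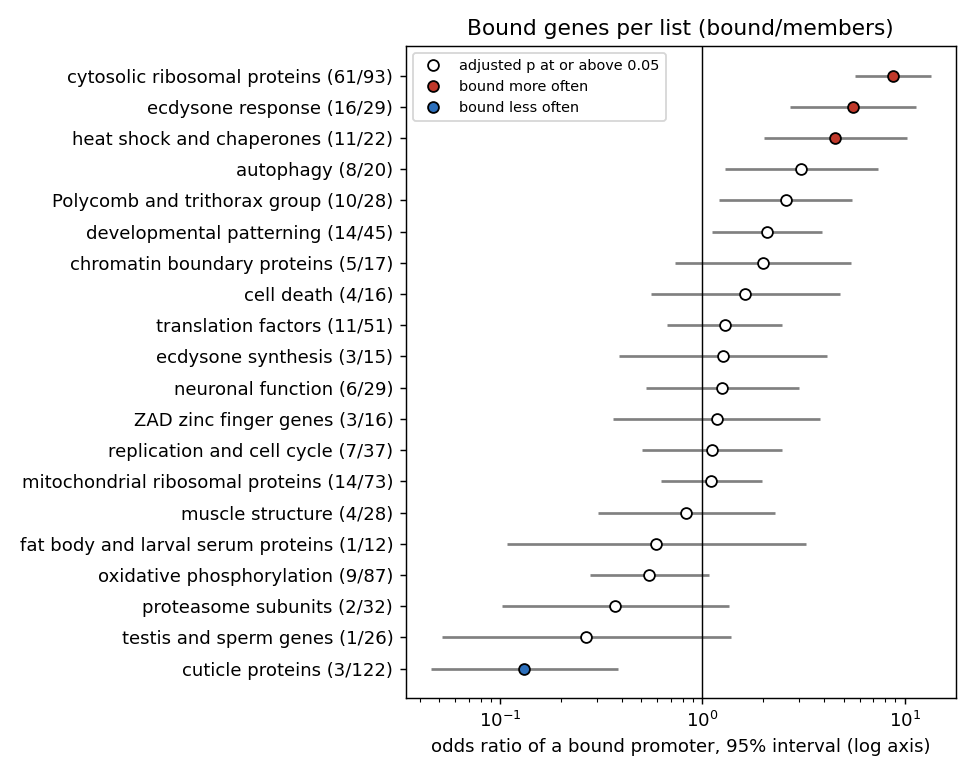
Odds ratio of a bound promoter in each gene list against all other protein-coding genes (horizontal log axis, 95% intervals), with bound and total members in brackets. Filled points passed the adjusted threshold, red for more and blue for less often bound. Lists with 0 bound genes are left out. Cytosolic ribosomal protein genes stand highest, at 8.77.

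Divergent promoters were bound more often than others. Of 5052 genes with a head-to-head TSS within 1000 bp, 24.5% were bound, against 14.4% of 8893 other genes (odds ratio 1.92, 95% interval 1.76 to 2.10, p = 3.05e-48, Fisher's exact test). A single summit can mark both genes of such a pair as bound, while the interval and p-value take genes as independent. The replicate lists gave odds ratios of 2.06 ± 0.234 (SD, n = 3). Overlapping promoter windows were also merged into regions. Of these, 672 of 2497 with start sites on both strands and 1567 of 10629 with 1 strand were bound (odds ratio 2.13). Start sites on both strands were counted in any arrangement there, so this is no recount of head-to-head pairs alone. In a logistic model with the log of region length, added after the data were seen, the odds ratio for both strands was 1.25 (95% interval 1.10 to 1.42).

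Peak windows of 100 bp on either side of the summit were compared with windows matched for GC content and for lying in a promoter or not. Controls outside promoters were not matched for coding sequence or transposable elements. Coding exons held 13.9% of random summits against 0.606% of IDR summits. Annotated elements held 5.41% of the genome against 0.161% of IDR summits. The motif and 7-mer calls were not adjusted for this. Of 21 known motifs, 5 were more and 3 less frequent at peaks (Fisher's exact test, Benjamini-Hochberg adjusted). The GAGA factor motif was in 6.32% of peaks against 2.63% of controls (odds ratio 2.49, adjusted exact p = 4.74e-29), and in 6.39% ± 0.393 of the replicate windows (SD, n = 3). Motif 7 had an odds ratio of 1.71 (adjusted p = 4.83e-07), dCTCF 2.17 (0.000893) and Grainyhead 3.68 (0.00341), all by the exact test, and E-box motif 5 was in 7.96% of peaks against 6.70% of controls (0.00691). The lower motifs were Ftz-F1 (odds ratio 0.377), STAT (0.804) and the BEAF core (0.905). Of the 21 shuffled versions, 4 were higher and 4 lower, among them shuffled GAGA at 1.64 and shuffled dCTCF at 2.57. Grainyhead and E-box motif 5 each lost their call without any 1 replicate, with odds ratios of 2.20 to 2.82 and 1.14 to 1.16, and Ftz-F1 did without replicate 1 (0.535) or replicate 3 (0.533). Against flanks 500 bp away, the odds ratios of E-box motif 5 (0.935) and the BEAF core (1.03) fell on the other side of 1. DRE, the DREF motif (2.13), Motif 1 (2.03) and the TATA box (1.49) were higher at peaks than in these flanks. The flanks were not matched for lying in a promoter. Against the matched controls, DRE (0.842), Motif 1 (1) and the TATA box (1.02) had no call.

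Among 8192 7-mers, 287 were more and 429 less frequent at peaks (Fisher's exact test, Benjamini-Hochberg adjusted). Against flanks these counts were 342 and 1053. The 5 with the highest odds ratios were CACAGTG (3.82, 6.45% of peaks against 1.77% of controls), CAGTGTA (3.59), CAGTGCA (3.54), ACAGTGG (3.43) and CACTGAG (3.16). All 5 contain CACTG or its reverse complement CAGTG, as did 26 of the 287 (9.06%) against 48 of all 8192 (0.586%). They did not centre on the summits. Within the windows their median distance from the summit was 60 to 63 bp, and the density of the core within 30 bp of summits was 0.644 times (0.603 to 0.688) that at 60 to 140 bp. At 60 to 140 bp, copies in the orientation with CACTG on the left and CAGTG on the right outnumbered the opposite orientation 2565 to 1935, a ratio of 1.33 (1.25 to 1.41), and by 1.25 to 1.26 in the replicate lists.

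**Figure D3:**
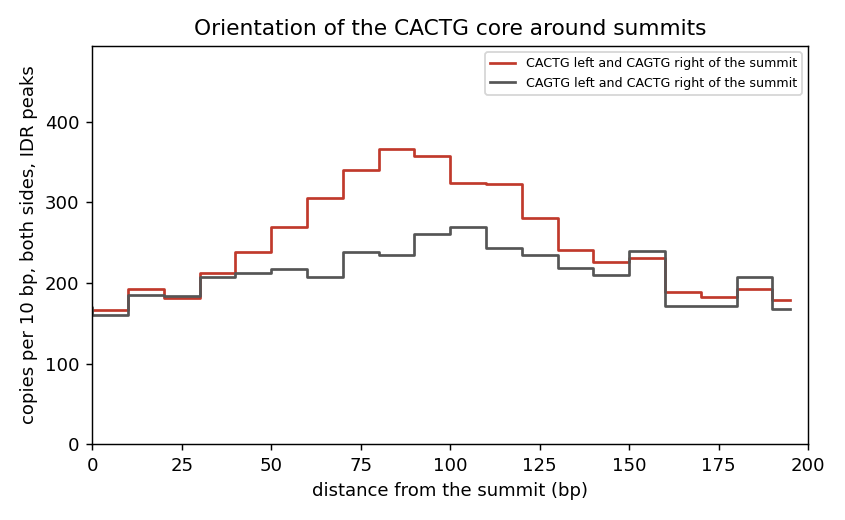
Copies of the CACTG core per 10 bp (vertical axis) at each distance from the summit (horizontal axis, bp), summed over both sides of all IDR peaks. The red line is CACTG on the left with CAGTG on the right, and the grey line the opposite orientation. The red line rises from 166 at the summit to 366 copies at 80 bp.

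Within 30 kb of Zaf1 itself there were 9 IDR peaks, and 0 lay within the gene. Their number per kb stood at the percentile 85.4 among protein-coding genes. The strongest, of signal 1041 and rank 682, was at the promoter of Csk, the C-terminal Src kinase gene (3R, 11646885 to 11647226), 21401 bp from Zaf1. Nearest was a peak of signal 163 in an intron at 3893 bp (3R, 11617338 to 11617807). The replicate lists had 7, 7 and 10 regions there, and 5 to 6 of the 9 peaks were matched when 1 replicate was left out.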

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

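The dm3 IDR list held 6 peaks on sequences outside the 6 arms, 4 on Uextra, 1 on U and 1 on XHet. That is above the fixed floor of 3 for listing such a count, and no test was made of it. The dm3 lists of 30000 regions held 25 to 39 such regions each. The dm6 lists held 0 such regions, and these sequences were in no comparison.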

How the results depend on the processing

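The 1000 strongest peaks, merged peaks, peaks without the inward-facing core, the lowest-ranked regions as controls and the values without 1 replicate for IDR peaks and Zaf1 were alternatives chosen after the data were seen. Of 101 alternatives to the main results, 74 left them on the same side of the threshold or within the spread. The top of the pooled list and merging summits within 100 bp changed nothing by construction. The cause was not tested for the values below, except that fewer peaks or genes enter the smaller sets. The share of regions found in another replicate was 55.4% at 50 bp, 79.4% at 250 bp, 80.6% for any overlap, 78.3% in lists of N/2, 58.0% in lists of 2N and 68.2 to 71.4% without 1 replicate. The correlation was 0.879 as Pearson's r of log2 signal, 0.794 at 250 bp and 0.824 to 0.829 without 1 replicate. Without 1 replicate, 5287 to 5634 IDR peaks and 5 to 6 peaks near Zaf1 were matched. The X ratio was 1.02 on dm3, with arm lengths taken to the last region, and 1.19 per TSS. The signal difference at promoters was 11.2 with a 250 bp window (permutation p = 0.0640), 50.6 to 76.2 without 1 replicate and 78.5 in peaks matched in every replicate.

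Changed gene lists numbered 0 with the 1000 strongest peaks (6 at an unadjusted p under 0.05 by Fisher's exact test), 10 with the nearest TSS only and 3 with the background limited to genes with a pooled region. The odds ratio of ribosomal protein genes was 5.03 (peaks without the inward-facing core) to 12.1 under 12 alternatives and 0.732 with the 1000 strongest peaks. Heat shock genes also lost their call with a 250 bp window (3.01), and the Polycomb and trithorax list gained one without each replicate (3.02 to 3.31), in peaks matched in every replicate (3.22) and without the inward-facing core (2.93), as did autophagy without replicate 3 (3.55) and, as lower, oxidative phosphorylation without replicate 1 (0.2996) and in peaks matched in every replicate (0.319). With the nearest TSS only, patterning (2.64) and Polycomb and trithorax genes (3.25) gained a call as higher and proteasome (0.0876) and oxidative phosphorylation genes (0.379) as lower, and glue genes gained one as lower with a 1000 bp window (0.0861). Changed motifs numbered 5 to 6 without 1 replicate, 4 with the 1000 strongest peaks and 4 with 50 bp windows. Changed 7-mers numbered 445 in the stronger part, 63 in the 1000 strongest, 252 with 50 bp windows, 1395 against flanks and 1784 against the lowest-ranked regions, while the 5 named ones kept their call in all 55 alternatives. Some odds ratios changed sides of 1 with a call in the main setting, the alternative or both. These were DRE (2.13 against flanks, 3.39 against the lowest-ranked regions), the BEAF core (1.03 and 1.22), E-box motif 5 (0.935 and 0.980, and 0.982 with 50 bp windows), Motif 6 (2.56 against the lowest-ranked regions) and STAT (1.13). DRE and Motif 6 had no call in the main setting. A change of side does not show that the alternative passed in the other direction. Against flanks and the lowest-ranked regions, Motif 1 (2.03 and 3.78) and the TATA box (1.49 and 1.65) gained a call, and against the latter the heat shock element did (2.45). Neither flanks nor lowest-ranked regions were matched for lying in a promoter. Promoters held 14.9% of the lowest-ranked summits against 35.3% of IDR summits. A further 27 list values and 43 motif values changed sides of 1 with no call in either setting. Depth was unknown, so how far it limits weak peaks cannot be given.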

Other observations

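Other gene types were counted after the data were seen, and their shares were not tested against the 18.1% of protein-coding genes. A summit lay within 500 bp of 35 of 290 tRNA genes (12.1%, 95% Wilson interval 8.81 to 16.3%), 17 of 269 snoRNA genes (6.32%, 3.98 to 9.89%) and 368 of 3261 other noncoding RNA genes (11.3%, 10.2 to 12.4%). It lay near 11 of 268 pseudogenes (4.10%), 1 of 32 snRNA genes (0.554 to 15.7%) and 0 of 99 rRNA genes, which are repeated copies. Among the 1000 strongest peaks, mitochondrial ribosomal protein genes (7 of 73, odds ratio 3.06) and Polycomb and trithorax group genes (4 of 28, odds ratio 4.97) had the lowest p-values of the lists that lay above other genes, and neither passed (both adjusted p = 0.135, Fisher's exact test).

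Of the tests that follow, those of the core sequence, the ribosomal protein genes, and the choice and position of the 8-mer were chosen only after the result was seen. The transposable element test was written before its result was seen. The design has 1 group, so no biological explanation was tested, and no untagged sample was analysed here.

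The sequence GGGCAGCA within 50 bp of the summit marked the strongest peaks, with 27 of the 300 strongest and 27 of 7791 others, and those peaks included MEP-1, c12.2, Atox1, CG33632 and DCTN4-p62. In windows on 2L and 2R, which favour central sequences, it tied for the lowest p with GCTGCCCA and was taken because it holds GCAGCA, a family noticed on all arms. A chance choice is argued against by its adjusted exact p of 6.33e-21 over all 32896 8-mers on all arms, with no sequence picked beforehand, while its odds ratio of 36.6 (17.9 to 74.7) on the other arms is no independent test, and GCTGCCCA (55.9 there) overlaps it on the opposite strand. The density of GGGCAGCA within 30 bp of summits was 16.5 times (4.33 to 62.6) that at 60 to 140 bp in the strongest peaks of those arms. This cannot decide on a preference at fragment ends. The 8-mer was sought within 50 bp of summits, and its family was noticed on all arms. Of the 27 summits, 0% lay in an annotated transposable element (upper Wilson limit 12.5%), which argues against copies of such an element. Such elements held 0.161% of all IDR summits and 5.41% of the genome. Copies that are not annotated stay open, and a sequence recognised by the tagged protein or a partner is a further candidate explanation that was not tested.

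The CACTG core lay beside the summits of the whole IDR list, where the density ratio was 0.644 (0.603 to 0.688). This argues against a core bound at the called summits. It cannot exclude a bound core between close summits, since these were not merged and such a core counts beside both. On dm6, 768 neighbouring summits were under 250 bp apart. In the 1000 strongest peaks the density ratio was 0.450 (0.371 to 0.547), and in the lowest-ranked regions 1.10 (1.03 to 1.18). In the 300 strongest it was 0.876 (0.658 to 1.17), below the 1.2 set for a core bound at the summit. A core bound there stays open, since the interval includes 1. CAGCACTG, which holds the core, was more frequent at the strongest summits of 2L and 2R (9 of 117 against 17 of 2727, adjusted exact p = 0.00354). On all arms it was in 28 of 300 against 46 of 7791 (adjusted exact p = 5.78e-18). GGCAGCAC (32 and 43 there) overlaps both CAGCACTG and GGGCAGCA. At the strongest summits the core and the 8-mer GGGCAGCA may therefore be parts of 1 longer sequence. GGGCAGCA matches the start of the consensus of Motif 7, KNNCAKCNCTRNY, and CAGCACTG matches its middle. Motif 7 was more frequent at IDR peaks than in matched controls (odds ratio 1.71), so both may be parts of that listed motif. Whether they lie side by side in the same peaks, as that motif would have them, was not tested. A sequence preference at the ends of sequenced fragments may give the mirrored orientation, and the orientation ratio of 1.33 in IDR peaks goes with it, but the lowest-ranked regions had 1.08 (1.00 to 1.16), which is not alike. With orientation ratios of 0.836 (0.628 to 1.11) in the 300 strongest peaks and 1.00 (0.863 to 1.16) in the 1000 strongest, end preference in all or only in weak regions cannot be told apart from other sources, since neither reads nor fragment ends were analysed here.

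Binding at ribosomal protein genes may come from technical sources. Oxidative phosphorylation, proteasome and translation factor genes together had an odds ratio of 0.684 (0.438 to 1.07) against 8.77 (5.72 to 13.4). This argues against a general pull-down of strongly expressed housekeeping promoters that takes in those families. They were pooled after their counts were seen, so this is no independent test. The heat shock and chaperone list went the other way (11 of 22, odds ratio 4.55). In the lists of replicates 1, 2 and 3, 76.3%, 58.1% and 54.8% of ribosomal protein genes were bound. Of all protein-coding genes, 18.3% ± 2.19 (SD, n = 3) were, which argues against dependence on 1 replicate. Among IDR peaks matched in both other replicates, the lowest odds ratio was 6.13 (4.07 to 9.23). The IDR list drew on all replicates, so this value cannot test such dependence. The inward-facing core was in 31.8% of the 66 peaks at ribosomal protein genes and 22.9% of 2794 other promoter peaks (odds ratio 1.59, 0.946 to 2.68). Without all peaks that hold it, the odds ratio of these genes was 5.03 (3.34 to 7.57). This argues against that core as the whole source and leaves a part open. Transcript level was not measured in these samples, so an effect of very high expression specific to these genes stays open.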
